A study of Mus musculus with 12 samples.

How the data were processed

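Messenger RNA of glycosylation genes was measured by quantitative real-time PCR in 12 mouse dendritic cell samples, in 4 groups of 3 deposited samples each. Per the labels' protocols, RNA was isolated with a spin-column kit, 50 to 100 ng was reverse transcribed, and the cDNA was amplified with SYBR Green on a commercial array plate of 96 wells. The plate holds 84 panel genes, 5 reference wells and a set of control wells. Each sample file deposited by the authors lists the threshold cycle (Ct) of each well, the cycle at which fluorescence passes a set line, so that a lower Ct means more template. The deposited series matrix holds, per gene, Ct minus the Ct of the beta-actin well, which is a log2 scale on which a higher value means less RNA. The authors also deposited a table of fold changes, a ratio of test over control after normalization to beta-actin per the file header. How Ct thresholds and baselines were set is not given in the sources used here.

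Wells were named by matching each plate position to the series matrix within 0.002 cycles. The symbols of 84 genes were found in the RefSeq gene table given with the data, and 1, Wbscr17, was found there as a synonym. The files name the first reference well as Actb and do not name the other 4. The manufacturer's usual layout places B2m, Gapdh, Gusb and Hsp90ab1 in wells H02, H03, H04 and H05, and those names are used here on that basis. In the third file of the splenic group and the second file of the tumor group, each value stood 1 well early. Moving them by 1 well raised the correlation across genes with another splenic file from 0.528 to 0.975 and from 0.565 to 0.883. They were used after this move, which loses the first well. The series matrix kept the unmoved values, and counted 13 blank wells of the second tumor file as 0 cycles.

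The third file of each group was not a separate measurement in its values. In 334 of 360 wells compared it equalled a constant times the mean Ct of the group's other 2 files, within 0.002 cycles. The mean was divided by 1.1 in unstimulated and by 1.08 in TGF-beta DC2.4 cells, and multiplied by 1.021 in both DC1 groups. The highest match of any other combination, among 660 tested, was 3 wells. The design set before the data were examined named all 12 deposited samples. After this relation was seen, the tests were limited to the 8 separately measured samples, 2 per group, and the fit on all 12 files became an alternative. Genes were left out where the third file broke this relation, or where values of the first splenic file in wells G06 to G12 were whole numbers or repeated another well. This removed 11 genes from the TGF-beta comparison and 17 from the tumor comparison, St6galnac1 from both, and St8sia4 and St8sia6 from the tumor comparison. Among them, A4gnt in the third unstimulated file stood at 36.7713, the first file's 40.4484 divided by 1.1, although the second file held 39.812. Some wells of the 8 samples thus appear to hold values other than those behind the third file, and why was not tested.

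Ct values over 35 and blank wells were set to 35. The tested value was the mean Ct of the 5 reference wells minus the gene's Ct, a log2 relative level. A gene was tested where its Ct was under 35 in at least 2 of the 4 samples compared. Each comparison was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The difference between the comparisons, and between both control groups, was a contrast in a fit on all 8 samples. Of 14 enzyme lists fixed before the data were examined, each with at least 3 tested genes was tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Reference wells were each set against the mean of the other 4 wells and tested by exact permutation. Parsing and plots used Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

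Named genes followed a rule set before the data were examined. For each main comparison these were the 12 largest changes per direction past the threshold, and 13 fixed genes where tested (St3gal1, St3gal2, St6gal1, St6galnac1, St8sia4, St8sia6, Neu1, Neu3, Mgat5, Mgat3, Fut8, Ogt and C1galt1). For the interaction they were the 6 smallest p, and for the control groups the 5 largest per direction. Other genes named were chosen after their values were seen. Alternatives changed the reference wells, the treatment of late Ct, the filter, the samples fitted, the variance model, the source of the values and the samples left out. On simulated data with the residual spread of the TGF-beta comparison over 69 genes, limma recovered 4.2%, 31.0% and 49.0% of genes changed by log2 1, 2 and 3. For the tumor comparison over 62 genes it recovered 3.2%, 27.8% and 53.2%. The panel holds none of the lineage markers listed in advance. No sequence was aligned and no coordinates were used.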

Results

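Expression of glycosylation genes was measured by quantitative PCR in mouse dendritic cells from 2 settings. DC2.4, an immortalized mouse dendritic cell line, was left unstimulated or treated with TGF-beta for 4 days. The labels give the dose as 2.5 ng/ml in one protocol and as 10 ng/ml in another. Type 1 dendritic cells (DC1), the subset specialised in cross-presentation to CD8 T cells, were sorted from spleen or from MCA101 fibrosarcomas grown under the skin of mice. The labels name XCR-1 for the splenic cells and CD103 for the tumor cells, so tissue and sort marker cannot be told apart. Each group had 3 deposited samples, of which the third held values computed from the first 2, so n = 2 separately measured samples per group. The labels do not say that these came from separate cultures or animals, and p-values then measure only the spread between these samples, which may be technical. In the separately measured samples, between 64 and 76 of 84 genes had a threshold cycle (Ct) under 35, and the median Ct of those genes lay between 22.8 and 30.8. In DC2.4 cells it followed the replicate number. It was 26.23 and 27.54 in replicate 1 of the unstimulated and treated groups, and 23.0 and 22.8 in replicate 2. Relative levels followed the replicate number too in some genes, such as St6gal1 and Pofut1, and not in others, such as Galnt3. The fits held no term for replicate, so such differences counted as spread between samples, and no fit with that term was run.

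The first comparison asked which glycosylation genes differed in DC2.4 cells treated with TGF-beta. No gene passed the threshold, and the 5 genes with the smallest p stood just short of it. B4galt1, which adds galactose to N-glycans, was 9.67-fold higher with TGF-beta (log2 fold change 3.27 ± 0.42 SE, n = 2 per group, adjusted p = 0.053). Galnt3 and Galnt6, which place the first sugar of mucin-type O-glycans, were 10.5-fold (log2 3.40 ± 0.49) and 6.74-fold higher (log2 2.75 ± 0.43). Mgat4a and Mgat5, which add branches to N-glycans, were 9.20-fold (log2 3.20 ± 0.50) and 9.79-fold higher (log2 3.29 ± 0.49), and these 4 genes also had an adjusted p of 0.053. In all 5 genes both treated samples lay above both unstimulated samples, which a choice by smallest p favours. Over all 69 genes tested, the groups did not overlap in 27, and 33.3% of genes would be apart by chance.

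No gene of 69 tested passed the limma test at an adjusted p of 0.05, and 11 had an unadjusted p under that value, 10 higher and 1 lower with TGF-beta, where chance would give 3.5. Besides the 5 above, these were C1galt1, which forms the T antigen on O-glycans (log2 fold change 1.88 ± 0.40 SE), B3gnt3 (3.88 ± 0.89), B4galt5 (3.34 ± 0.85), Neu1 (3.0 ± 0.87), Galnt9 (3.38 ± 1.04) and, as the lower one, Neu3 (-2.04 ± 0.54). Neu1 is the lysosomal sialidase and Neu3 the sialidase of the plasma membrane. Neu1 was 4.06 and passed without TGF-beta replicate 1, and was 1.95 and did not pass without replicate 2. B3gnt3 (4.94), B4galt5 (4.35) and Galnt9 (4.40) passed without TGF-beta replicate 2, and without replicate 1 were 2.82, 2.32 and 2.35 and did not pass. Galnt9 was 4.21 and 2.54 without unstimulated replicate 1 and 2. Neu3 was -2.36 without TGF-beta replicate 2 and -1.73 without replicate 1, and -1.67 and -2.42 without unstimulated replicate 1 and 2. Mgat5 was 3.39 and 3.19 without TGF-beta replicate 2 and 1, and 3.68 and 2.90 without unstimulated replicate 1 and 2. With all 6 deposited files entered as separate samples, 14 genes passed, 12 higher and 2 lower, but the computed files carry no spread of their own. A fit that shared its spread over all 8 measured samples called 6 genes and a prior that was robust and followed a trend 7. Without TGF-beta replicate 1 the count was 4, and without TGF-beta replicate 2 it was 15. The median of all tested genes was 0.29, and moved between -0.52 and 0.80 with the choice of reference wells. Relative to that median, B4galt1 was 2.98, Galnt3 3.11 and Mgat4a 2.91 higher, and the 11 genes kept their sign under each of 11 choices of reference wells.

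The remaining genes chosen in advance showed smaller or more scattered differences. Among sialyltransferases, which cap glycans with sialic acid, St3gal1 had a log2 fold change of -0.03 ± 0.50, St3gal2 of 0.31 ± 0.82, St6gal1 of -0.19 ± 0.63 and St8sia4, which makes polysialic acid, of 1.02 ± 0.64. St8sia4 was 0.34 without TGF-beta replicate 1 and 1.7 without replicate 2. The signs of St3gal1, St3gal2, St6gal1 and Fut8, the core fucosyltransferase (log2 0.16 ± 0.54), turned with the choice of reference wells. St8sia6 was at Ct 35 or later in both unstimulated samples and at 29.3 and 34.2 in the treated samples. With the unstimulated samples set to Ct 35, its fold was at least 15.7, but the treated samples were far apart and its adjusted p was 0.82. Mgat3, which adds the bisecting branch, had a log2 fold change of 2.88 ± 1.62, and Ogt, the enzyme that places O-GlcNAc on intracellular proteins, of -3.64 ± 1.60. None of these passed (adjusted p between 0.41 and 0.98), but single samples decided 2 of them. Mgat3 was 4.70 and passed without TGF-beta replicate 2, and was 1.05 and did not pass without replicate 1. Ogt was -5.74 and passed without TGF-beta replicate 1, and was -1.53 and did not pass without replicate 2.

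By the lists fixed in advance, the enzymes that add galactose and extend polylactosamine were the group with the highest median in DC2.4 cells. Its 7 measured members had a median log2 fold change of 3.27 with TGF-beta, with 0 past the threshold over all genes and 1 when adjusted over the list alone (camera adjusted p = 0.29, and 0.93 with an estimated correlation). The 11 GalNAc transferases had a median of 0.43, with 2 past the threshold when adjusted over the list alone, and the 6 Mgat enzymes of N-glycan branching had a median of 1.58, also with 2 (camera adjusted p = 0.88 and 0.57). A test for change in either direction within a list, fry's mixed test, gave an adjusted p of 0.016 for each of these 3 lists. It does not compare a list with the other genes. The 10 lysosomal glycosidases had a median of -0.39 (camera adjusted p = 0.29), and Fuca1, the lysosomal fucosidase, had a log2 fold change of -1.80 ± 0.69. Its relative log2 levels were -6.63 and -5.15 in the treated samples and -4.33 and -3.85 in the unstimulated ones. The 6 enzymes of O-glycan core extension had a median of 0.14, below that of the other genes, though their mean was 0.96 and camera placed them higher (adjusted p = 0.88), with 2 members past the threshold when adjusted over the list alone.

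No list passed camera in this comparison. The median log2 fold change was 0.66 over 6 sialyltransferases, 0.15 over 4 fucosyltransferases, 0.20 over 9 enzymes of ER and Golgi trimming and 0.38 over 7 of ER quality control. It was 0.00 over 3 genes of mannose 6-phosphate tagging, 0.38 over 3 of O-fucose, O-glucose and Fringe glycans, and 0.40 over 3 of O-mannose glycans. Camera's adjusted p for these lists lay between 0.80 and 0.88. The mean of the trimming enzymes was -0.01, and camera, which compares a list with the other genes, placed trimming, quality control, fucosyltransferases, mannose 6-phosphate tagging and O-mannose enzymes lower despite medians of 0 or above. Sialidases had 2 tested members, Neu1 and Neu3, of opposite sign, and O-GlcNAc cycling had 1, Ogt, so neither list was tested.

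The second comparison asked how glycosylation genes differed between DC1 from tumor and from spleen. Its direction is not settled, because the sample files and the authors' deposited table run opposite ways. Across 62 genes, log2 fold changes from the files and from the tumor columns of the authors' deposited table had a Spearman correlation between -0.97 and -0.96. The directions here follow the sample labels, and the sign of each DC1 value would turn if the labels of the files were exchanged. In the samples labelled tumor, 5 genes of 62 were lower and 0 higher than in those labelled splenic. Galnt6 was 22.5-fold lower (log2 fold change -4.49 ± 0.70 SE, n = 2 per group, adjusted p = 0.015) and Galnt3 was 14.8-fold lower (log2 -3.89 ± 0.77, adjusted p = 0.020), both of them initiators of mucin-type O-glycans. Galnt3 was at Ct 35.1 in the first tumor sample, set to 35, so its fold is a bound. Its call was lost with late Ct left out (log2 -3.34) and without tumor replicate 1 (log2 -3.34).

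B4galt5, a galactosyltransferase of glycolipids, was 9.71-fold lower in the samples labelled tumor (log2 fold change -3.28 ± 0.60, adjusted p = 0.020). B3gnt8, which extends polylactosamine on branched N-glycans, was 14.8-fold lower (log2 -3.88 ± 0.75, adjusted p = 0.020). Neu2, a cytosolic sialidase, had the largest difference (log2 -7.56 ± 1.22, adjusted p = 0.015). It was at Ct 26.2 and 26.8 in the splenic samples, at 32.8 in the first tumor sample and blank in the second, so its fold of 189 is a bound set by Ct 35. Its log2 fold change was -5.72 with late Ct left out or without tumor replicate 2, and -9.40 without tumor replicate 1, and it passed in each. With all deposited files it was -1.66 and did not pass. In a fit on all 8 measured samples 6 genes passed, all lower, and these shared 3 of the 5 genes, since B3gnt8 and Neu2 did not pass there. B4galt5 did not pass without tumor replicate 1 or 2, though its log2 fold change was -3.27 and -3.29, and B3gnt8, at -3.14, did not pass without tumor replicate 2. In the authors' deposited table, Galnt6 was listed at 17.5, 15.3 and 13.6 for tumor over spleen, B4galt5 at 7.57, 8.15 and 7.91, and Neu2 at 1.12, 1.06 and 1.12, so that Neu2 had no such difference there.

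All 5 genes stayed lower under each of 11 choices of reference wells, at highest between -5.59 for Neu2 and -1.31 for B4galt5. Neu2 passed in all 11, Galnt6 in 10, and Galnt3, B3gnt8 and B4galt5 in 9. With the B2m well alone only Neu2 passed, though Galnt6 was -4.76, Galnt3 and B3gnt8 -4.15 and B4galt5 -3.54. With the Gapdh well alone Galnt3 and B3gnt8 (both -1.91) and B4galt5 did not pass. Another 7 genes were lower and 1 higher at an unadjusted p under 0.05. The lower ones included Neu1 (log2 fold change -2.57 ± 0.67, adjusted p = 0.062), B4galt1 (-2.63 ± 0.69, adjusted p = 0.062), Man1c1, a Golgi mannosidase (-2.81 ± 0.77, adjusted p = 0.066), Mgat4a (-2.09 ± 0.63), Mgat5 (-2.25 ± 0.70, adjusted p = 0.095) and B3gnt3 (-2.78 ± 0.89). The higher one was Fuca1 (1.77 ± 0.71, adjusted p = 0.21). Man1c1 had the same sign with TGF-beta (-1.01 ± 0.59), and the other 6 named here had the opposite sign. Without splenic replicate 2 the 6 lower ones named lay between -3.99 for B3gnt3 and -2.38 for Mgat4a. Without splenic replicate 1 they lay between -2.32 for Neu1 and -1.56 for B3gnt3. Fuca1 was 2.45 without splenic replicate 1 and 1.09 without splenic replicate 2. The reference wells moved the count most, from 1 with the B2m well alone to 38 with the Gusb well alone. The median of all tested genes was -0.39 and ranged from -1.32 to 1.58 over these choices. It did not account for the counts, since the Actb and Gusb wells alone both gave -1.32, with 11 and 38 genes passing. With the mean of all panel genes as reference, 20 genes passed, 9 higher and 11 lower, and with the Gapdh well alone 16 passed, 14 higher and 2 lower. With late Ct set to 40 none passed, though Galnt6, B4galt5 and B3gnt8 kept their log2 fold changes and Galnt3 was -6.39 and Neu2 -10.06. With all 6 deposited files 21 passed. Without splenic replicate 1 the count was 12, without splenic replicate 2 it was 16, and without tumor replicate 1 or 2 it was 3.

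Relative to the panel median, Galnt6 was -4.10, Galnt3 -3.49, B3gnt8 -3.49 and B4galt5 -2.89 in the samples labelled tumor. Of the sialic acid genes chosen in advance, St3gal1 had a log2 fold change of -1.15 ± 0.62, St3gal2 of -0.07 ± 0.76, St6gal1 of 0.79 ± 0.80 and Neu3 of 0.74 ± 0.76. Mgat3 had -1.48 ± 0.75, Fut8 0.38 ± 0.69, Ogt 0.75 ± 0.98 and C1galt1 -0.25 ± 0.73. None of these 8 passed (adjusted p between 0.30 and 0.98), and each turned its sign with the choice of reference wells. St6gal1 and Fut8 passed in 2 of the 11 choices, St3gal1, Neu3, Mgat3, Ogt and C1galt1 in 1, and St3gal2 in 0. B4galt2 was blank in both separately measured tumor samples and at Ct 30.7 and 29.5 in the splenic ones, and was left out because the computed tumor file gave it a value.

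The list of galactosyl and polylactosamine enzymes again stood at an end of the panel. Its 5 measured members had a median log2 fold change of -2.63 in the samples labelled tumor, with 2 past the threshold over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.32, and 0.99 with an estimated correlation). Of 9 GalNAc transferases, 2 were lower and 7 did not pass, with 2 when adjusted over the list alone. Of 3 sialidases, 1 was lower and 2 did not pass, with a median of -2.57 (camera adjusted p = 0.96) and 2 when adjusted over the list alone. The 6 Mgat enzymes had a median of -0.91, with 0 past the threshold and 2 when adjusted over the list alone. Fry's mixed test gave an adjusted p of 0.038 for the galactosyl list, 0.048 for GalNAc transferases and 0.038 for the 10 lysosomal glycosidases, whose median was -0.14.

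No list passed camera in the DC1 comparison. The median log2 fold change of the GalNAc transferases was -0.11 with a mean of -0.76. The medians were -0.54 over 6 enzymes of O-glycan core extension, -0.23 over 9 of ER and Golgi trimming, -0.15 over 6 of ER quality control and -0.58 over 4 fucosyltransferases. They were -0.64 over 3 genes of mannose 6-phosphate tagging, -0.40 over 3 of O-fucose, O-glucose and Fringe glycans, -0.32 over 3 of O-mannose glycans and -0.07 over 3 sialyltransferases. Camera's adjusted p for these lists lay between 0.96 and 0.98. Of these lists, only GalNAc transferases had members past the threshold over all genes. Camera placed GalNAc transferases, lysosomal glycosidases, trimming, quality control, fucosyltransferases, O-mannose enzymes and sialyltransferases higher than the other genes, against the negative sign of their medians. O-GlcNAc cycling had 1 tested member, Ogt.

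**Figure D1:**
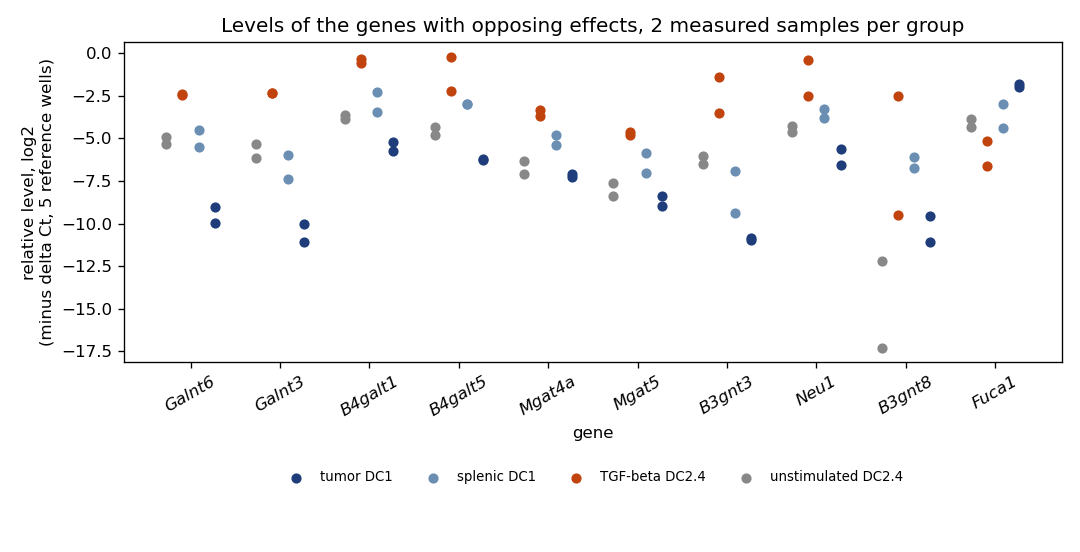
Relative level on the log2 scale (minus delta Ct against 5 reference wells) of 10 genes whose effects differed between the comparisons. Each point is 1 of the 2 separately measured samples of a group, and in all genes but Fuca1 both TGF-beta samples lie above both unstimulated samples and both samples labelled tumor lie below both splenic samples. The genes were chosen by the test of the difference, which favours such separation, so it is no further support.

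The third comparison tested whether the effect in DC1, as labelled, differed from the effect of TGF-beta in DC2.4 cells. Of 61 genes, 10 had effects that differed (limma interaction contrast), 9 of them lower in DC1 than in DC2.4 and 1, Fuca1, higher. The difference between the log2 fold changes was -7.24 ± 0.88 SE for Galnt6 (adjusted p = 0.00033), -7.28 ± 0.97 for Galnt3 (adjusted p = 0.00041), -5.90 ± 0.86 for B4galt1 and -6.62 ± 0.99 for B4galt5 (both adjusted p = 0.00059). It was -5.29 ± 0.83 for Mgat4a (adjusted p = 0.00069) and -5.54 ± 0.90 for Mgat5 (adjusted p = 8e-04). B3gnt3, Neu1 and B3gnt8 also passed. The split of 9 lower and 1 higher rests on the reference wells, since with the mean of all panel genes as reference 14 genes passed, 9 lower and 5 higher (Fuca1, Man2b1, Neu3, St6gal1 and Ogt). With the labels of the DC1 files exchanged, the effects of these genes would have the same sign in both comparisons, and each of the 10 differences would be smaller. B4galt5, for one, had a log2 fold change of 3.34 with TGF-beta and -3.28 in DC1 as labelled, and Galnt6 of 2.75 and -4.49. The count of 10 thus rests on the labels, and the contrast was not tested with them exchanged.

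Across these 61 genes, which are not independent replicates, the effects had a Pearson correlation of -0.70 and a Spearman correlation of -0.49. Without the 10 genes that passed, the Pearson correlation over the other 51 genes was -0.19. Those 10 were picked by the difference between the same effects, so removing them by itself weakens a negative correlation. The value thus does not show that the other genes are unrelated. Effects had opposite signs in 39 genes and the same sign in 22. With the labels of the DC1 files exchanged, these 2 counts would trade places and the correlations would be positive. No gene passed the threshold in both separate comparisons, since none passed with TGF-beta, and the overlap expected by chance was 0.

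**Figure D2:**
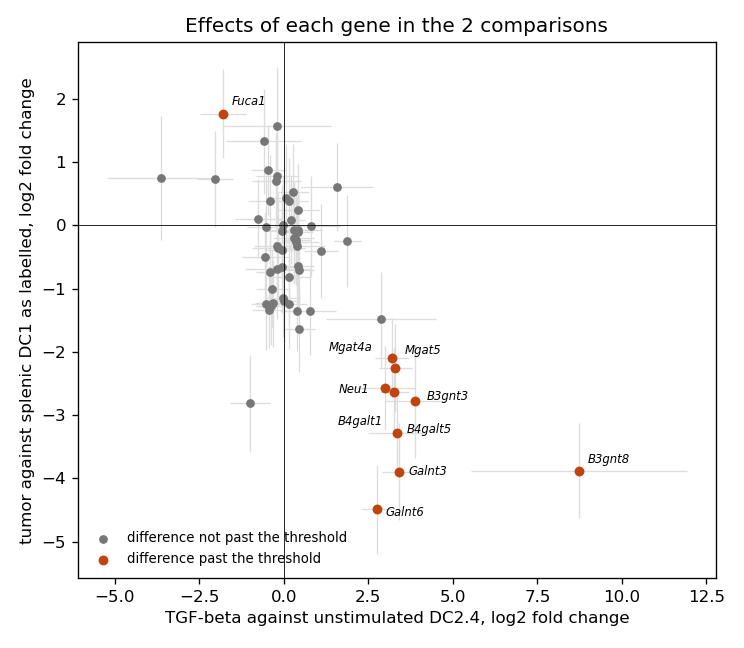
Log2 fold change of each of 61 genes with TGF-beta in DC2.4 cells (x axis) and in the samples labelled tumor against splenic DC1 (y axis), with SE bars and n = 2 per group. The 10 genes with a difference past the threshold are named, and 9 of them lie at lower right, between -4.49 for Galnt6 and -2.09 for Mgat4a on the y axis.

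Relative levels rest on the reference wells, which were not equally stable. In DC1, the well usually holding Gapdh, a glycolytic enzyme, was 2.46 cycles later in the samples labelled tumor relative to the mean of the other 4 reference wells (2.19 ± 0.15 SD against -0.27 ± 0.10, n = 2 per group). The Actb well was earlier by a difference of -1.15 cycles and the usual Gusb well by -1.16. The usual B2m and Hsp90ab1 wells differed by -0.33 and 0.18 cycles. These small differences do not make them stable, since both wells had the largest spread between the splenic samples, with SDs of 1.81 and 1.41 cycles. In DC2.4 cells, the treated samples differed from the unstimulated ones by 0.64 cycles in the usual B2m well, -0.36 in the Gapdh well, -0.16 in the Actb well and -0.06 each in the Gusb and Hsp90ab1 wells, with an exact p of 0.67 or 1 for each well. An exact permutation test over the 6 assignments of 4 samples cannot give a two-sided p under 0.33, which the Gapdh, Actb and Gusb wells reached in DC1.

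**Figure D3:**
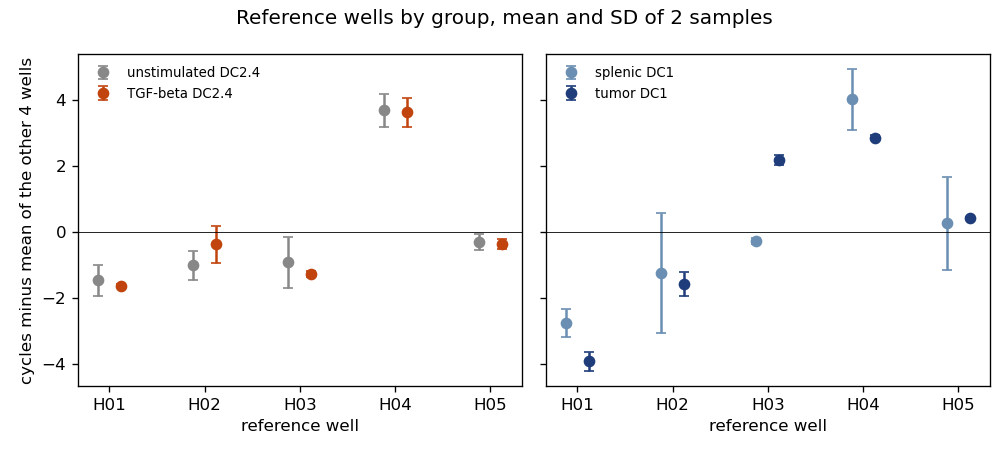
Ct of each reference well minus the mean of the other 4 wells, in cycles, as mean and SD of 2 samples per group, for DC2.4 cells on the left and DC1 on the right. The wells are H01 (Actb) and, by the usual layout, H02 (B2m), H03 (Gapdh), H04 (Gusb) and H05 (Hsp90ab1). In DC1 the H03 well stands 2.46 cycles apart between the groups.

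For DC2.4 cells the authors' deposited table and the files ran the same way across 69 genes. Pearson correlations lay between 0.92 and 0.94 and Spearman correlations between 0.87 and 0.96. The table and the files come from the same samples, so this is no independent support. The 3 columns had the sign of the files in 55, 45 and 67 genes. These counts, unlike a correlation, move with a constant shift. Per the file header the deposited folds were normalized to beta-actin, whereas the values from the files used 5 reference wells. In the third column, however, St3gal1 and C1galt1 stood at 0.975 and 3.69, against 0.977 and 3.68 from the files with 5 wells. With the Actb well alone St3gal1 had a log2 fold change of -0.16, not -0.03. These values do not bear out beta-actin alone as the reference of that column. In the authors' deposited table, the second DC2.4 column was 0.627 times the first in the median gene, and 97.6% of 83 genes lay within 0.02 of that ratio. B4galt1 was listed at 8.20, 5.14 and 9.80 with TGF-beta in the authors' deposited table, and Galnt6 at 5.95, 3.73 and 6.79.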

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

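The test of the difference between the effects was set in advance, whereas the tests of explanations for the opposite signs, for the authors' fold table and for the third files were chosen only after those results were seen.

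With the DC1 labels as given, the effects on 10 genes differed between the comparisons by a test of the difference itself. Each difference would be smaller with those labels exchanged, which was not tested. The difference between the tumor and TGF-beta log2 fold changes was -7.24 for Galnt6, -7.28 for Galnt3, -5.90 for B4galt1, -6.62 for B4galt5, -5.29 for Mgat4a and -5.54 for Mgat5. The genomic DNA control well of the first tumor DC1 sample, which no comparison used, gave a Ct of 34.18, while the other separately measured samples were blank there or later than Ct 40.

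The opposite sign of these genes in both comparisons, with the DC1 direction taken from the labels, was weighed against 3 technical explanations. With the mean of all panel genes as reference, 10 of the 10 genes stayed past the threshold among 14 that passed, which argues against a shift of the reference wells, and without the tumor file that had been moved by 1 well the correlation across genes was still -0.66, which argues against that move. An exchange of tumor and splenic labels in the files is a candidate explanation, as the tumor columns of the authors' fold table correlated with the files at -0.81 or lower. A biological difference between sorted cells and a cell line stays open and was not tested.

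That the tumor columns of the fold table run opposite to the files was weighed against 2 technical explanations. An inversion of the whole table is argued against by its DC2.4 columns, which correlated with the files at 0.92 or more. An exchange of tumor and splenic labels, either in the files or in those columns, is a candidate explanation for the correlation of -0.81 or lower. No value here decides between these places, and an exchange in the columns alone would not bear on the opposite signs, which come from the files. No biological explanation was tested for the table.

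The third file of each group was weighed against 3 explanations. A repeat run of the same RNA would scatter by at least the SD of the control triplicates, 0.03 cycles or more. Of 360 wells compared, however, 334 lay within 0.002 cycles of the scaled mean. The median distance from it, at most 2.7e-05 cycles, decides nothing further. It was taken over wells already within 0.002 cycles and could not have reached that SD. An equal pool of both RNAs would follow the pooled template. The median distance from it, after a constant offset, was taken over wells more than 2 cycles apart between the other files. It was above the triplicate SD of each group, at 0.152 cycles or more over at least 62 wells outside the tumor group. In the tumor group it was 0.068 cycles over 5 wells, against an SD of 0.06, which hardly tells a pool apart. Arithmetic on the other files accounts for 92.8% of the wells. No biological explanation was tested.

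The 4 samples of each comparison can be split into pairs in 3 ways, the real grouping included, which is too few for a share under 0.05. With TGF-beta, 3 of the 3 splits gave as many genes, as the real count and the highest other count were both 0. In the DC1 comparison, 1 of the 3 splits, the real grouping itself, gave 5 genes, and the highest other count was 0.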

How the results depend on the processing

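The main fit on 8 samples and the leaving out of genes with inconsistent wells were chosen after seeing the data, in place of the design set in advance, which named all 12 deposited files. The fit on all deposited files, with every well kept, holds the samples of that design and was made an alternative only then. The fit that kept genes with inconsistent wells, and the use of the Actb well alone for the interaction, the correlation and the baseline, were also chosen after seeing the data. With 1 sample left in a group, that sample was assumed to vary like the other groups. Where no reason is given, the cause of a change was not tested.

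With TGF-beta, the count of 0 genes was kept under all choices of reference wells, late Ct set to 40 or left out, no filter, array weights and the fit with all wells. It was 5 with Ct under 35 in every sample, 5 with Ct under 30 in at least 2 samples (fewer genes tested in both), 6 in a fit on all 8 samples, 7 with a trend and robust prior, 12 with series matrix values and 14 with all deposited files, and 0 to 15 without single samples. For tumor against splenic DC1, the count of 5 became 11 with the Actb well alone, 1 with B2m, 16 with Gapdh, 38 with Gusb and 15 with Hsp90ab1. It was 12 without B2m among the references, 11 without Gapdh, 9 without Hsp90ab1 and 20 with the mean of all panel genes. It was 0 with late Ct set to 40, 3 with Ct under 35 in every sample, 3 with Ct under 30 in at least 2, 9 with a trend and robust prior, 9 with array weights, 0 with series matrix values and 21 with all deposited files, and 3 to 16 without single samples. The log2 fold change of Neu2 turned to 0.88 with series matrix values, in which blank wells count as 0 cycles and 2 files are not moved.

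The 10 interaction genes became 18 with all deposited files and stayed within 9 to 12 without single samples. The correlation of -0.70 was -0.65 with late Ct at 40, -0.73 with all deposited files, -0.64 with all wells kept and between -0.71 and -0.64 without single samples. No gene list passed, except 1 without TGF-beta replicate 2 and 1 without tumor replicate 1, a range of 0 to 1. The 7 baseline genes became 13 with the mean of panel genes, 29 with all deposited files and 3 to 9 without single samples. The shift of the Gapdh well stayed between 2.36 and 2.57 cycles without single samples. Over the genes named by the rule, 50 alternative values newly passed the threshold, 24 no longer passed, and 44 turned sign with no pass on either side. In simulated TGF-beta data with 2 samples per group, 31.0% of genes changed by log2 2 and 49.0% of those changed by log2 3 were recovered, and no other number of samples was simulated.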

Other observations

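The control groups of both settings were run on the same panel, and sorted splenic DC1 as labelled differed from unstimulated DC2.4 cells in 7 of 61 genes, all higher in splenic DC1 (limma on 8 samples). The largest were B3gnt8 (log2 difference 8.30 ± 1.98 SE, n = 2 per group, adjusted p = 0.016), Galnt12, a GalNAc transferase (at least 6.86 ± 1.21, adjusted p = 0.0048, with the first unstimulated sample at Ct 36.6 set to 35), Fut8, the core fucosyltransferase (3.64 ± 0.64, adjusted p = 0.0048), Galnt10 (3.30 ± 0.93, adjusted p = 0.042) and Fut11 (3.06 ± 0.69, adjusted p = 0.013). St3gal1 (2.57 ± 0.58, adjusted p = 0.013) also passed. Gcnt1, which branches O-glycans, was -2.75 ± 0.85 and did not pass (adjusted p = 0.062). With the mean of all panel genes as reference 13 genes passed, 7 higher and 6 lower, when Gcnt1 passed (adjusted p = 0.045) and Galnt10 did not (adjusted p = 0.055). Culture, sorting and plates differ together between the cell line and the sorted cells.

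Several genes were far apart between samples of a group. With TGF-beta, B3gnt8 had a log2 fold change of 8.73 ± 3.19, with relative log2 levels of -2.49 and -9.52 in the treated samples and -12.18 and -17.29 in the unstimulated ones. Ogt stood at -5.96 and -10.17 in the treated samples and at -4.14 and -4.71 in the unstimulated ones. Uggt1, a sensor of glycoprotein folding, stood at -7.03 and -2.04 in the treated samples and at -4.58 and -5.25 in the others. Neu2 was left out of that comparison, with Ct values of 23.8 and 34.5 in the treated samples.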
